A study of Arabidopsis thaliana with 2 samples.

How the data were processed

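Rosette leaves of Arabidopsis thaliana Col-0 were profiled on 2 Affymetrix arrays with 1 colour (biotin), 1 array per group. Per the labels, plants were grown on compost at 22 °C under 24 h of light after 1 week of stratification at 4 °C and were at growth stage 3.5. The treatment label, given for the NOT sample, states that each sample pools 4 experiments with RNA from about 8 leaves in each, and the series' design text gives 8 pooled plants. The extraction label speaks of seedlings where the tissue label names rosette leaves, and this difference was left open. Group codes NOT and WDC come from the sample titles, which the labels do not explain, so ratios are given in a fixed direction, NOT over WDC.

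The deposited values are 1 intensity per probe set and array on a linear scale, without detection calls. They had been scaled by the authors before deposit, as judged from the values: the mean after trimming 2% at each end was 100.1 on both arrays. The software that summarised probes into probe sets is not given in the sources used here. Median signals were 22.0 in NOT and 23.7 in WDC, and 1 and 2 values were listed at 0. Per the labels, the scanner background averaged 75.02 in NOT and 76.78 in WDC, and the noise 2.38 and 2.67. As 1 array was hybridised per group, the number of arrays limits the precision and no p-value was computed.

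Genes were named through a table of the platform's annotation, whose names were updated by locus through a RefSeq gene table of assembly TAIR10.1, used for names and gene order only. Of 8297 probe sets, 50 controls were left out. Of the other 8247, 3794 named 1 gene, 70 several and 4383 none here, and 3784 of the first were matched to the RefSeq table. They covered 3592 genes. Probe sets with several genes or none entered the probe-set counts without a name.

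The floor was the 40th percentile of the pooled non-control values, 12.5. A log2 ratio was taken for 4753 probe sets above it on both arrays, with no offset. A further 141 lay above it on NOT only and 242 on WDC only, for which the brighter value over the floor is a lower bound of the fold, and 3111 lay above it on neither. Counts used a 2-fold rule and gene groups a 1.5-fold rule. A gene with several probe sets was given by the brightest. Gene groups with at least 3 measured members were described by the median log2 ratio and its percentile among 10000 random lists of the same size, matched in 20 bins of mean signal. The script used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 (loess with a span of 0.4) and matplotlib 3.10.9.

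Named genes were fixed by rule before the data were examined, as were the floor, the fold rules and the groups. The rule took the 12 highest and 12 lowest log2 ratios among genes named by 1 probe set or more, the 4 largest bounds in each direction, up to 4 members of each group with the largest absolute ratio, and 25 fixed genes, of which 0 had a named probe set in the table used here. In all, 34 groups had been fixed, 25 by locus and 9 by family name. Of 631 loci listed, 46 had a named probe set and 38 were measured. 10 groups had at least 3 measured members, 9 had 1 or 2, and 15 had none. Those with none were nitric oxide metabolism, nitrogen uptake and assimilation, iron homeostasis, phenylpropanoid and flavonoid synthesis, the morning clock, markers of root, flower and pollen, seed, guard cells, vasculature and dividing cells, reference genes, cytosolic ribosomal proteins, aquaporins and class III peroxidases by symbol. Family rules on gene descriptions could be applied to symbols and synonyms only.

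A further 5 classes by locus and 5 families by symbol were written after the highest and lowest genes had been seen and are described in the closing section. From the class of oxidative and mitochondrial stress, 1 locus (AT2G32200) was taken out after its value was seen, because its membership rested on no known function. A class of cysteine-rich receptor-like kinases was dropped for having no named probe set.

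Alternatives were median scaling, quantile normalization, loess on mean signal, floors at the 25th and 60th percentiles, an offset of a fixed part of the floor, leaving out probe sets marked for shared sequence, 1.5-fold and 3-fold rules, scaling to the spiked-in controls (added after the results were seen), the mean over probe sets of a gene and random lists without matching. Leaving out shared probe sets also lowered the floor, from 12.5 to 10.6. The counting script was tested on simulated data for NOT over WDC with noise of SD 0.2 on the log2 scale, in which 4850 probe sets were above the floor. It called 97 of 100 probe sets with a 3-fold change, 99 of 100 with a 4-fold change and 0 of 4631 unchanged ones. A simulated list of 20 genes at 1.5-fold, more than any group measured here, returned a median fold of 1.53. Changes were placed only on signals well above the floor, and the noise was equal at all signals. It stood for probe noise and not for variation between plants or hybridisations. The real log2 ratios had an SD of 0.49. These rates therefore test the script and do not give the error of the real counts.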

Results

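Transcript levels were measured in rosette leaves of Arabidopsis thaliana, accession Col-0, in a series on how nitric oxide acts in plants. Nitric oxide is a gaseous signalling molecule that plants make and respond to. RNA from 2 pooled samples was hybridised to 2 oligonucleotide arrays of 8297 probe sets, 1 array in the group coded NOT and 1 in the group coded WDC. The labels do not spell out these codes and tie neither of them to the control they mention, so every ratio is the signal in the NOT array over that in the WDC array and neither array is called treated. With 1 array per group no difference has a replicate check, and the number of arrays limits the precision of every value.

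Among named genes above the signal floor on both arrays, AT2G21640 had the lowest ratio of NOT over WDC and AT4G37520 the highest. AT2G21640, which encodes UPOX, a mitochondrial protein known to be induced by oxidative stress, had a signal of 15.7 in the NOT array and 260.8 in the WDC array, 16.6-fold lower in NOT. DREB2C, a transcription factor of heat and drought responses, was 7.09-fold lower in NOT, and AT1G59860, a small heat shock protein, was 5.86-fold lower. The NOT signals of AT2G21640 and DREB2C (18.9) lay near the floor of 12.5, so the sizes of these folds are uncertain. In the opposite direction AT4G37520, a class III peroxidase of the cell wall, had a signal of 156.4 in NOT and 29.1 in WDC, 5.37-fold higher in NOT. The transcription factor WRKY53, a regulator of leaf senescence and defence, was 3.21-fold higher in NOT, and the chitinase CHI (AT2G43570) was 2.76-fold higher.

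Of 4753 probe sets above the signal floor on both arrays, 67 were at least 2-fold higher and 158 at least 2-fold lower in NOT. The lower ones made up 70.2% of these, with shares of 81.4%, 71.4%, 69.9% and 58.7% over 4 equal classes of probe sets from the dimmest to the brightest. With the arrays scaled to the spiked-in controls, an alternative chosen after the results were seen that moved the median log2 ratio of all probe sets to 0.14, 103 were higher and 123 lower (54.4% lower). Counted as named genes, 21 were at least 2-fold higher and 57 at least 2-fold lower among 1934. Of the 2-fold probe sets, 45 of the 67 higher and 98 of the 158 lower had no name here, so named genes leave out most of them. The median log2 ratio over all probe sets was 0.00, with quartiles of -0.24 and 0.22. Across probe sets, which are not independent replicates, the log2 signals of both arrays had a Pearson r of 0.964 and a Spearman rho of 0.955. For 93 genes measured by more than 1 probe set, the log2 ratios of probe sets of the same gene scattered with an SD of 0.19, which covers probe noise and not the variation between plants. With the floor at the 25th percentile the counts were 106 higher and 242 lower, and at the 60th percentile they were 43 and 81.

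The 12 highest named genes had log2 ratios from 1.17 to 2.43. UGT72E1, a glucosyltransferase, had signals of 303.0 in NOT and 106.3 in WDC, a log2 ratio of 1.51. CCOAMT (AT1G67980), a methyltransferase of the caffeoyl-CoA type, had a log2 ratio of 1.28. The class V chitinase ChiC (AT4G19810) had a log2 ratio of 1.26, and the peroxidase AT5G39580 one of 1.18. The glutathione transferase GSTF3 gave 1041 in NOT and 450.1 in WDC, a log2 ratio of 1.21, on a probe set that is marked as shared within its gene family. The probe sets of AT4G37520 and AT4G24340 carry a mark for shared or similar sequence too, so related genes can contribute to their signals. GLL23 (AT1G54010), AT4G24340, AT1G10690 and AT2G41190 completed the group, with log2 ratios of 1.86, 1.62, 1.28 and 1.17. The WDC signals of AT5G39580 (14.0) and AT2G41190 (13.6) lay close to the floor of 12.5, which leaves the sizes of their ratios uncertain.

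The 12 lowest named genes had log2 ratios from -4.05 to -2.18. AT4G39670, a protein of the glycolipid transfer family, was 9.83-fold lower in NOT, with signals of 33.6 and 330.3. AT2G32030, an acetyltransferase of the GNAT family, was 8.41-fold lower, and its NOT signal of 12.9 lay close to the floor of 12.5. AT2G41380, a methyltransferase-like protein, was 7.85-fold lower, with signals of 72.0 and 565.3. AT4G24160, an acyltransferase of lysophosphatidic acid, was 6.26-fold lower and AT1G24140, a matrix metalloproteinase, 5.35-fold lower. AT1G75280, an isoflavone reductase-like protein, was 4.79-fold lower and AT1G05340 4.55-fold lower. AT1G23710 and AT2G32200 had log2 ratios of -2.89 and -2.42. The probe sets of DREB2C and AT4G24160 are marked for shared sequence, so the same limit holds for them.

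**Figure D1:**
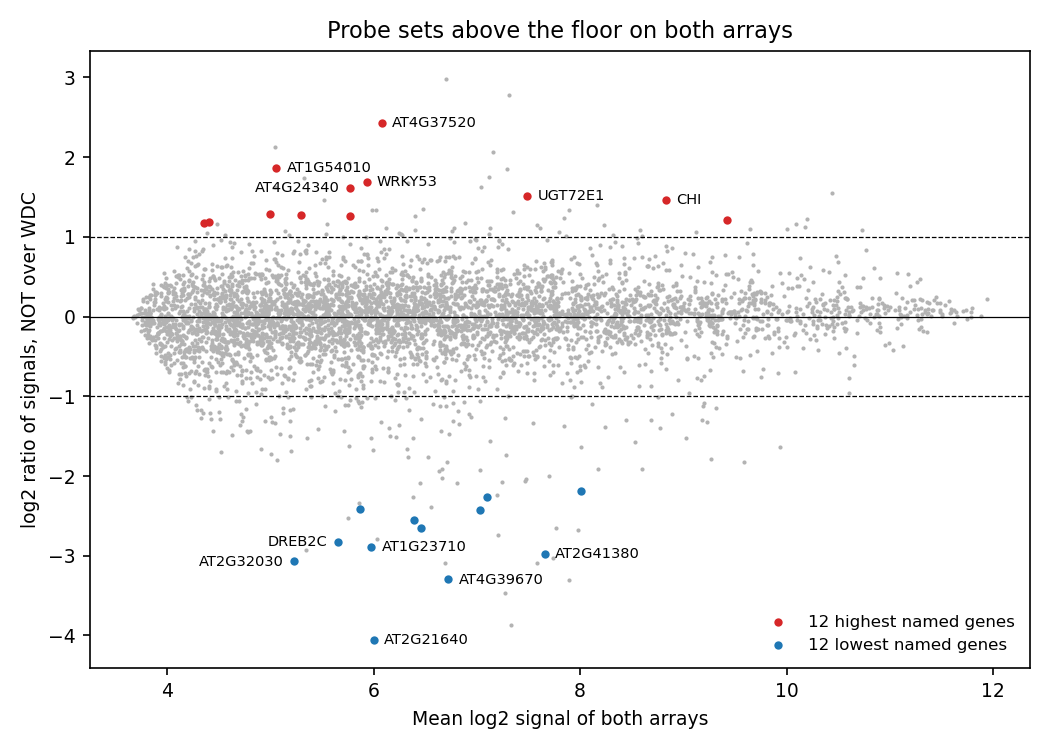
Each point is 1 of the 4753 probe sets above the floor on both arrays, with its mean log2 signal on the horizontal axis and the log2 ratio of signals, NOT over WDC, on the vertical axis. Red and blue points are the 12 highest and 12 lowest named genes, dashed lines mark 2-fold, and 67 grey or coloured points lie at or above the upper line against 158 at or below the lower one.

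Some genes lay above the floor on 1 array only, for which a bound is given, the brighter signal over the floor. PR-1-LIKE (AT2G19990), related to the defence protein PR1, was at least 5.30-fold lower in NOT, with 66.2 in WDC. AT2G39650, on a probe set marked for shared sequence, was at least 5.26-fold lower, the glucosyltransferase UGT73C1 at least 4.46-fold lower and AT2G32020, another GNAT acetyltransferase, at least 3.82-fold lower. AT4G07820 was at least 3.07-fold higher in NOT, AT4G35160 at least 2.48-fold, AT2G42760 at least 2.35-fold and AT4G15260 at least 2.17-fold. In all, 11 probe sets had a bound of at least 2-fold higher and 38 a bound of at least 2-fold lower in NOT.

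The photosynthesis genes measured here had nearly equal signals on both arrays. All 7 measured of 48 listed genes of light harvesting and the photosystems lay within 1.5-fold, with a median log2 ratio of 0.05. So did all 6 measured of 31 listed genes of the Calvin cycle and photorespiration, with a median of 0.04. Without shared probe sets 3 and 4 genes of these groups stayed measured, all within 1.5-fold. PSAN, a subunit of photosystem I, had a log2 ratio of -0.23 and SBPASE, sedoheptulose bisphosphatase of the Calvin cycle, one of -0.30. Of 5 antioxidant enzymes, 1 was at least 1.5-fold higher in NOT and none at least 1.5-fold lower. This was the glutathione reductase GR (AT3G54660), at 0.96 on a probe set marked for shared sequence, while the other glutathione reductase, GR1, stood at -0.51 and the peroxiredoxin AT3G11630 at -0.54 (-0.59 and past the 1.5-fold rule with loess). Of 3 measured genes of heat shock and chaperones, 1 was at least 1.5-fold lower (2 of 4 with the 25th percentile floor and without shared probe sets). The added gene was AT1G53540, with signals of 11.5 in NOT and 20.5 in WDC, which passed the lower floors of these settings, 4.3 and 10.6. Hsp70-2, a cytosolic chaperone, had signals of 307.2 in NOT and 882.9 in WDC, a log2 ratio of -1.52, and its second probe set gave -1.30. AT3G09440 stood at -0.15, and its second probe set gave -0.61, past the rule. The small heat shock protein AT2G29500 had signals of 18.8 in NOT and 24.3 in WDC, a log2 ratio of -0.37, within 1.5-fold. Another small heat shock protein, AT1G59860, at -2.55, was not in the list fixed before, so the group values leave it out. Of 4 genes of abscisic acid, drought and cold, the dehydrin LTI30 was lower by the 1.5-fold rule, at -0.66 on a probe set marked for shared sequence (-0.51 and short of the rule with control scaling), and COR15B, COR47 and KIN2 stood at -0.18, -0.15 and 0.03. The probe sets used for AT3G11630, COR47 and KIN2 carry a mark for shared or similar sequence too. Without such probe sets, fewer than 3 genes stayed measured in the antioxidant and abscisic acid groups.

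WRKY53 was a member of several groups and set the upper end of each. Of 4 measured genes of leaf senescence, 1 was at least 1.5-fold higher (WRKY53, 1.68) and 1 at least 1.5-fold lower (WRKY6, -0.61), and the autophagy gene APG8A and the vacuolar protease GAMMA-VPE stood at 0.46 and 0.36. WRKY6 fell short of the 1.5-fold rule with median scaling (-0.57), the offset (-0.58) and control scaling (-0.46), and with control scaling APG8A passed it (0.60). Of 3 genes of the rapid touch, wound and elicitor response, WRKY53 was higher, EXO, a cell wall protein of growth control, was lower at -1.15, and the zinc finger factor STZ stood at -0.44 (-0.68 and past the rule without shared probe sets). Among 7 WRKY factors, WRKY53 was higher and WRKY6 lower by the 1.5-fold rule, with WRKY20 at 0.36 and WRKY22 at -0.43. Of 7 expansins and xyloglucan transglucosylases, enzymes and proteins that loosen cell walls, 3 were at least 1.5-fold lower and none at least 1.5-fold higher. They were EXPA8, 2.01-fold lower, EXPA4, 1.65-fold lower, and XTH32, 1.61-fold lower. With control scaling EXPA4 and XTH32 fell short of the rule (log2 ratios of -0.58 and -0.55), which left 1 of the 3. The 3 measured histone genes lay within 1.5-fold, with HIS4 at -0.52, and without shared probe sets fewer than 3 stayed measured. The probe sets of HIS4 and GAMMA-VPE are marked for shared sequence.

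Groups with 1 or 2 measured genes are given by those genes. The lactate dehydrogenase AT4G17260, an enzyme of fermentation, had signals of 43.7 in NOT and 148.4 in WDC, a log2 ratio of -1.76 on a probe set marked for shared sequence, and the pyruvate decarboxylase PDC2 stood at -0.47. IAA18, an auxin-response repressor, had a log2 ratio of -1.17 and IAA20 one of -0.04. The P450 enzymes CYP71B6 and CYP71B28 stood at 0.52 and 0.49, and the glutathione transferase GSTU16 at 0.40. The clock gene GI, the ethylene-signalling factor EIN3 and the thionin THI2.1, a jasmonate marker, stood at 0.37, 0.30 and -0.24. The probe sets of CYP71B6, IAA20 and THI2.1 carry a mark for shared or similar sequence too. WRKY53 and DREB2C were the measured genes of the defence list and of the AP2/ERF family.

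Each group median was placed among the medians of 10000 random lists of the same size matched on signal, as a description of these 2 arrays. The leaf senescence genes, with a median log2 ratio of 0.41, lay at percentile 98.0, outside the central 95%. The other 9 groups with at least 3 measured genes lay inside it. Their medians and percentiles were -0.44 and 3.21 for the rapid touch response, -0.37 and 4.43 for heat shock, -0.28 and 5.65 for expansins and xyloglucan transglucosylases, and -0.17 and 3.06 for abscisic acid, drought and cold. For antioxidant enzymes, histones and WRKY factors they were -0.16 and 15.1, -0.19 and 24.7, and -0.02 and 52.8, and light harvesting and the Calvin cycle lay at percentiles 45.5 and 43.4. Placement near the limit depended on the setting, since the senescence genes lay inside under 4 alternatives (lowest percentile 92.7). The groups of heat shock, rapid touch, expansins and abscisic acid lay outside on the low side under 2 alternatives each (lowest percentiles 0.510, 1.03, 0.545 and 1.89), whereas against random lists without matching abscisic acid lay at percentile 22.9, and the WRKY factors under 1, the 60th percentile floor.

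**Figure D2:**
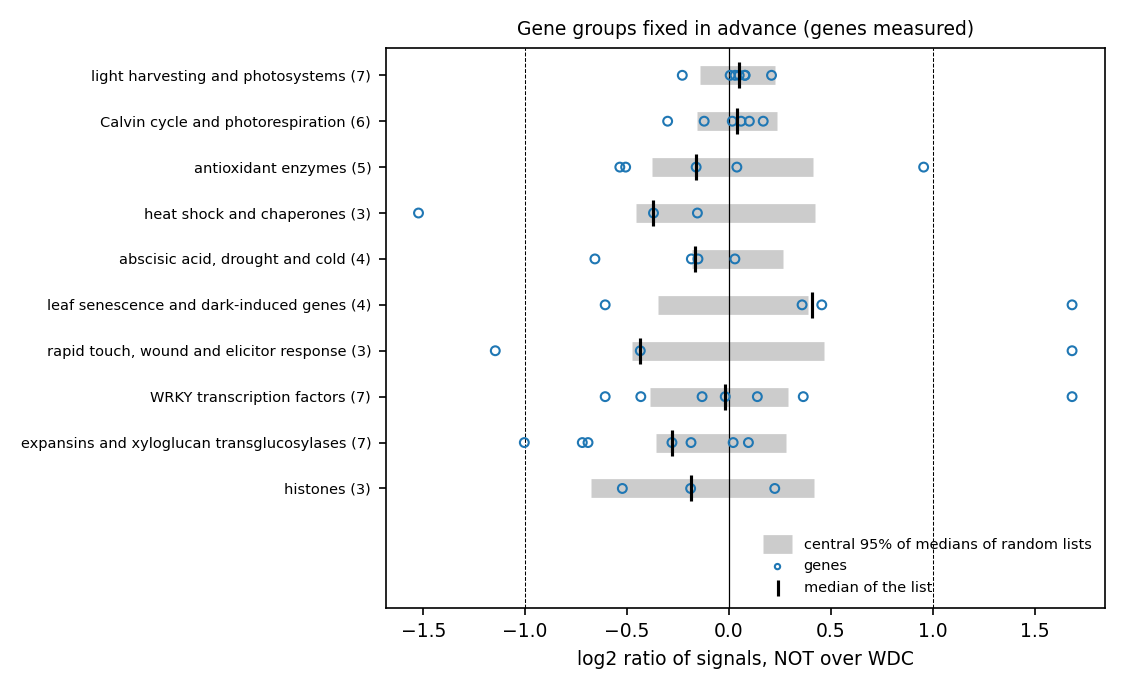
Log2 ratios of signals, NOT over WDC, of the genes measured in the 10 groups with at least 3 such genes (circles), with the median of each group (black bar) and the central 95% of medians of random lists (grey). The number of genes is in brackets. Only the leaf senescence median, 0.41, lies outside its grey range.

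Control probe sets described hybridisation and RNA quality on the arrays. The 9 spiked-in hybridisation controls, above the floor on both arrays, had a median log2 ratio of -0.14, from -0.28 to -0.03. For GAPDH the signal of the 3' probe set over that of the 5' probe set was 1.24 in NOT and 1.19 in WDC. For ubiquitin this ratio was 1.45 in NOT and 1.13 in WDC, while the ratio of the 3' over the middle probe set was 1.39 in NOT and 1.87 in WDC.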

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

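The added classes and families in this part (stress markers, peroxidases, chitinases, endoplasmic reticulum genes, glucosyltransferases, carboxypeptidases and MADS-box factors) and the scaling to spiked-in controls were chosen after the data had been seen, and the other alternatives had been fixed before. Among named genes that were 2-fold and still measured, and in the 2-fold counts, no direction turned, though some 1.5-fold calls of group members were lost or gained. The 12 highest and 12 lowest genes all stayed 2-fold the same way under 4 other scalings, the 25th percentile floor and the mean of probe sets. Only quantile normalization and loess could have changed these calls. Median and control scaling add a constant too small to undo them. A floor leaves measured ratios unchanged, and these genes had 1 measured probe set each. With the offset 10 of the 12 highest stayed 2-fold, and the 60th percentile floor left 3 and 4 of them measured and leaving out shared probe sets 9 and 10. At the 2-fold rule the share of lower probe sets ranged from 65.3% to 71.0%, except with control scaling, which gave 103 higher and 123 lower (54.4%). That scaling raised every ratio, with medians of 0.19 for light harvesting, 0.18 for the Calvin cycle, -0.025 for abscisic acid, drought and cold, 0.12 for glucosyltransferases, 0.27 for peroxidases, 1.11 for chitinases, 0.82 for endoplasmic reticulum genes and -2.04 for stress markers, and no group changed its place against the central 95% of random lists, nor did any against random lists without matching. A constant moves random lists equally, so control scaling could hardly change a place. The 1.5-fold rule gave 279 higher and 415 lower probe sets and the 3-fold rule 15 and 56, by construction. The 25th percentile floor gave 106 and 242 and a heat shock median of -0.60. The 60th gave 43 and 81, and medians of -0.43 for WRKY factors, -0.69 for expansins, 0.19 for glucosyltransferases and -1.91 for stress markers. Without shared probe sets the floor fell to 10.6, which alone moved the medians of heat shock (-0.60) and MADS-box factors (-0.38). Others were -0.68 for rapid touch, -0.49 for expansins, 0.43 for carboxypeptidases (percentile 98.0, outside random lists) and -0.11 for peroxidases. The glucosyltransferase and peroxidase medians thereby changed sign from -0.03 and 0.13, neither being outside random lists. Other small medians changed sign under some scalings, among them light harvesting (-0.03 with loess), the Calvin cycle (-0.03 with loess) and WRKY factors (0.03 with loess). The floors and the removal of shared probe sets measure fewer or other members, and no other cause was tested. Otherwise 163 values of gene groups moved by less than the spread of random lists or kept their side of its limits. Of named genes 543 values moved by less than the spread of probe sets of a gene and 15 by more, in the same direction. Most of the 543 had to, given constant shifts, floors or 1 probe set. Signal over background limits ratios near the floor.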

Other observations

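The gene classes in this part were written after the highest and lowest genes had been seen, and the tests of scaling, of signals near the floor, of RNA degradation and of class members not seen beforehand were chosen after the result was seen, but not the count of neighbouring gene pairs, the fold rules or the floors. Medians of whole classes are therefore not independent evidence of their direction. Chitinases, enzymes that cleave chitin of fungal walls, had 6 measured members, of which 5 were at least 1.5-fold higher in NOT and none lower, with a median log2 ratio of 0.97 and a percentile of 100 among random lists. Besides CHI and ChiC they were AT4G01700 (1.09), AT2G43590 (0.84, or 0.46 as the mean of its probe sets) and AT2G43620 (0.83). The values of all 5 had been seen when the class was written, so the percentile rests on genes known to be high, and the 1 member not seen beforehand, AT2G43610, stood at 0.27. Among 10 class III peroxidases 4 were at least 1.5-fold higher (1 of 5 measured without shared probe sets) and 1 lower (AT5G40150, -0.68, short of the rule with quantile normalization, the offset and control scaling), with a median of 0.13 at percentile 89.6. AT5G64120 had signals of 1627 in NOT and 727.2 in WDC, a log2 ratio of 1.16, and the 6 members not seen beforehand had a median of -0.13 at percentile 22.1. Of 3 measured proteasome genes, the subunit AT4G24820 and the assembly factor AT1G67250 stood at -0.87 and -0.75 and AT2G32730 at 0.39, with a class median at percentile 0.275. The values of both low genes had been seen, and the 1 member not seen beforehand, AT2G32730, had the higher signal in NOT.

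The families drawn by symbol with at least 3 measured members lay inside the central 95% of random lists, except the serine carboxypeptidase-like genes without shared probe sets. The 11 measured glucosyltransferases had a median of -0.03 at percentile 48.8, and UGT73B1 stood at -2.09 where UGT72E1 stood at 1.51. The 4 serine carboxypeptidase-like genes had a median of 0.20 at percentile 86.0 (98.0 without shared probe sets), the 3 AGAMOUS-like MADS-box genes -0.04 at 50.9 and the 5 trichome birefringence-like genes 0.08 at 71.5. Without shared probe sets the MADS-box median was -0.38, as AGL93, with signals of 11.9 in NOT and 20 in WDC, passed the lower floor of 10.6. The beta-glucosidases BGLU25 and BGLU33 stood at 0.75 and -0.53. Genes named in this part outside the fixed rule were chosen after their values were seen.

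More probe sets were 2-fold lower than 2-fold higher in NOT, and 3-fold lower (56) than 3-fold higher (15). Scaling stays open as a cause of the excess at 2-fold. Only 1 of 4 scalings removed most of it, the one chosen after the results were seen. The share of lower ones fell from 70.2% to 54.4% when the spiked-in controls, with a median log2 ratio of -0.14, were set equal. That step adds a constant to every log2 ratio, so the share had to fall, and it moved the median of all log2 ratios to 0.14. With median scaling, quantile normalization and loess the share was 67.1%, 65.3% and 69.9%. At 3-fold it was still 72.1% with the controls set equal, the lowest of 4 scalings. None of the 4 scalings removed the excess at 3-fold. Shifts as small as these could hardly do so, and a larger difference in scale was not tested. Signals near the floor stay open, as the share was 65.3% with the 60th percentile floor but fell from 81.4% in the dimmest to 58.7% in the brightest of 4 equal classes of probe sets. Unequal RNA degradation (3' over 5' ratios differed 1.04-fold for GAPDH and 1.28-fold for ubiquitin, whose 3' over middle ratio went the other way, 1.39 in NOT and 1.87 in WDC) and what the group codes stand for, as an untested biological explanation, also stay open.

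Of 9 measured genes of oxidative and mitochondrial stress, 8 were at least 2-fold lower in NOT, with a median log2 ratio of -2.18, and these 8 were known to be low when the class was written, among them ZAT7 (-1.91), AT4G01870 (-1.91) and AT4G13180 (-1.76). A candidate explanation is that this class as a whole differed between the pools. Its members not seen beforehand that were above the floor on 1 array or more were STZ, AT2G32020 and MSRB9. The signal was lower in NOT for 3 of 3, which is too few to decide. STZ, above the floor on both arrays, stood at -0.44, within 1.5-fold (-0.68 and past it without shared probe sets). AT2G32020 (6 in NOT and 47.7 in WDC) and MSRB9 (8.6 and 13.7) were above the floor in WDC only, which by itself sets their direction. AT2G32020 is also a GNAT acetyltransferase like AT2G32030, which was among the 8 known to be low.

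Of 6 measured genes of protein folding and quality control in the endoplasmic reticulum, 4 were at least 1.5-fold higher in NOT (3 with loess or the offset, and 3 of 5 measured without shared probe sets), with a median log2 ratio of 0.68 at percentile 99.99, led by ATERDJ2B, 2.15-fold higher, the calreticulin CRT1b, 1.84-fold higher, and DER2.1, 1.70-fold higher. This may be a shift of the whole class, but the 3 members not seen beforehand had a median of 0.24 at percentile 91.0, inside the central 95%, and 3 genes leave it open.

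The number of neighbouring gene pairs that were both 2-fold the same way lay within what shuffling gave. Of 336 pairs of adjacent measured genes 1 pair, AT2G32200 and AT2G32210 (log2 ratios -2.42 and -2.06), was 2-fold the same way, against a mean of 0.328 and a central 95% from 0 to 2 in 10000 shuffles of the ratios over genes.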
